A study of Drosophila melanogaster with 12 samples.

How the data were processed

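Carcasses of stationary larvae were dissected, with internal tissues removed, from wildtype larvae of the w1118 strain and from Nxt1 trans-heterozygotes listed under the strain yw. Staging used food with 0.05% bromophenol blue. Per the labels, 1 ug of total RNA was incubated with 20 units of RNase R in 25 uL at 37 degrees Celsius for 30 min, or mock-treated with water, and stranded libraries depleted of rRNA were read as pairs of 75 bases. The labels tie the 3 M libraries of each genotype to the mRNA and pre-mRNA values and the 3 R libraries to the circRNA values. They do not spell out the letters, which are read here as mock and RNase R. Whether replicates are separate pools of larvae is not stated, and replicates were treated as independent.

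The mRNA and pre-mRNA values are FPKM as deposited by the authors, per the labels, with 17492 genes in each table. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, Subread, featureCounts 1.6.2 and DESeq2, with no roles. Which part of a gene was counted as pre-mRNA is not stated, and the implied lengths point to introns, being equal, once put in order as below, to the gene span minus the exonic length in 2885 of 4476 genes compared. The genome build is not given in the sources used here, and no coordinates are printed. The circRNA values are raw counts of back-splice reads as deposited by the authors, per the file headers, beside the same counts scaled by the authors. Each listed circRNA carries the reads of 2 of the 3 libraries of its genotype, told apart by the library total that the scaled value implies. The scaling is to 1e+09 library reads, although the header gives the unit as BPM. A circRNA is named by its transcript and the numbers of its last and first exon. That reading of the name was inferred from the values: no first exon lies before exon 2 and no last exon before the first. The tool that called the circRNAs and the rule for listing one are not given in the sources used here.

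Gene IDs were matched to symbols with the reference table of the fly genome annotation, and 17370 of 17492 IDs had one. Within a gene the FPKM of the 6 libraries divide into whole-number ratios, so whole reads were recovered, with a tolerance of 0.01 for a whole count. All 15293 mRNA and 4543 pre-mRNA genes with finite values and reads gave whole reads, and those of 293 and 88 genes had to be multiplied by a shared factor. On simulated data, 97.1% of 14854 mRNA genes and 96.4% of 4381 pre-mRNA genes came back exactly. The deposited library factors of mRNA equal median-of-ratios size factors, from 0.593 (Nxt1 replicate 1) to 1.24 (WT replicate 1).

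The lengths used for the FPKM are out of order. Spearman's rho of the implied length with the gene's own span was -0.002 for mRNA and 0.021 for pre-mRNA, against 0.926 and 0.856 with the span of the gene at the same rank of the sorted IDs. In 3247 of 3371 mRNA genes checked the implied length equalled the latter, and in 0 of 3387 their own. A ratio of FPKM within a gene does not change with its length. A level, a filter on FPKM, the weight of a pseudocount and so a fold on FPKM + 1 do. In pre-mRNA 1757 genes are infinite in at least 1 library and 2878 are undefined in all, read here as lengths of 0 with and without reads, and they were left out. Of 6300 genes with pre-mRNA reads, 0 were found with an own intron length of 0. The infinite genes were thus left out through lengths of other genes. Intron lengths for the relation below were the implied lengths put back in order, or the span minus the exonic length where the value holding that length had no reads. Longest intron and intron number, planned as well, were not used here, since the sources used here give neither.

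Genes with a mean of at least 1 FPKM over the 6 M libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), eBayes with trend, genotype as the term, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The ratio of mRNA to pre-mRNA was the difference of both log2 values in a library, for genes that passed both filters. Folds are on FPKM + 1, levels are means with SD. The 31 gene lists, with 839 members of which 829 are in the tables, were fixed before the data were examined, with their test: camera of limma with a correlation of 0.01, over lists with at least 3 tested members, 29 for mRNA and 23 each for pre-mRNA and the ratio. Camera with an estimated correlation and fry, which tests a list against no change rather than against other genes, were run beside it. All lists, cell type markers included, were written from general knowledge with no source at hand, and which of the markers the carcass itself expresses was not known. Lsp1alpha is in the fat body list and among the largest rises, and Cpr65Av in the cuticle list.

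Named genes follow a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 FPKM for mRNA (1 for pre-mRNA and the ratio) and the genotypes fully separated. It adds Nxt1, w, y and tn with any result, and up to 4 members of each list with the largest fold past the threshold, or 2 with the largest fold if none passes. For circRNAs it takes the 8 highest in WT, the 5 largest rises and 5 largest falls past the threshold, and those of tn and mbl. Genes of 2 sets were counted under both. What a gene encodes is given from general knowledge.

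Host genes were tested with camera against all other genes and against 10000 random lists matched on mean expression. CircRNAs of both tables with at least 10 reads over the 4 values were tested with edgeR 4.0.16 (quasi-likelihood), with offsets from the deposited library totals. TMM normalization had been planned, but the columns mix libraries, so TMM factors and DESeq2 1.42.0 size factors, both computed from the scaled values, were alternatives. CircRNAs were matched between tables by transcript and exon numbers, since coordinates are not in the sources used here, and the planned tolerance of 5 bases at the ends was not run. Structure classes were compared with Fisher's exact test. Relations across genes used 100000 permutations. The relation of the ratio to intron length, the random lists matched on intron length and the recovered-read tests with edgeR were added after seeing the data, and so were the alternatives with equal totals, with lengths put back in order and with library effects taken out of the circRNA reads and circRNAs matched by gene and exon numbers. Sequences, isoforms and the infinite pre-mRNA values were not analysed here.

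The tests were run on simulated reads with the depth and spread estimated from these libraries, whose depth the report gives per library. For mRNA, limma called 59.2% of 2-fold and 91.7% of 4-fold changes, with 7.01% of calls false. For pre-mRNA it called 9.18% and 44.7% with 12.1% false, where edgeR on reads called 62.1% and 95.7% with 5.26% false. For the ratio limma called 4.12% and 38.5% with 2.38% false, and for circRNAs edgeR called 3.45% and 35.7% with 8.33% false. Low counts of calls in pre-mRNA, ratio and circRNAs are to be read against these shares. Of 1000 unchanged lists, 2.7% had a camera p under 0.05. Genes were simulated independently, so this share does not hold for lists of correlated genes. Oxidative phosphorylation, for example, had an estimated correlation of 0.853 in mRNA.

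Alternatives covered the pseudocount, the filter, quantile and median-ratio normalization, the replicate block, eBayes without trend, array weights and each M replicate left out, or for circRNA calls each reads column, which mixes libraries and is no replicate. In the table of alternatives, lists that did not pass in pre-mRNA or the ratio were dropped, and those that did not pass in mRNA are followed by their number of members past the threshold. This was decided after seeing that their signs, which carry no call, changed in 34 of 323 mRNA, 28 of 358 pre-mRNA and 20 of 376 ratio results, of which 2 in mRNA passed the threshold and are reported. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.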

Results

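Total RNA was sequenced from carcasses of stationary Drosophila melanogaster larvae of the third instar. The carcass is what stays after the internal tissues are removed. Larvae trans-heterozygous for Nxt1 mutations, which carry a different mutant allele on each homologous chromosome, were compared with wildtype larvae. Nxt1 is a small cofactor of the mRNA export receptor encoded by sbr, and the labels give its effect on circular RNA (circRNA) and on the balance of pre-mRNA, mRNA and circRNA as the question of the study. RNA of each genotype was used with RNase R, an exonuclease that degrades linear RNA and spares circles, or with water in its place. There were 12 libraries in 4 groups of 3. Below, WT and Nxt1 stand for the genotypes, and the 6 M libraries carried the mRNA and pre-mRNA values while the 6 R libraries carried the circRNA values.

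As recovered from the deposited values, the M libraries held 32305628, 31492056 and 30193498 reads assigned to mRNA in WT and 19830526, 32840337 and 32868851 in Nxt1. Reads assigned to pre-mRNA came to 1433407, 1455766 and 1237133 in WT and 664555, 1266425 and 1307520 in Nxt1. The 10 most abundant genes took 10.4%, 9.97% and 12.9% of mRNA reads in WT and 18.2%, 17.8% and 15.96% in Nxt1. The R libraries had totals of 69690700, 78830800 and 92273200 reads in WT and 48182700, 71326500 and 78946600 in Nxt1. In a principal component analysis of mRNA the first component, with 61.1% of the variance, separated the genotypes, and the second, with 20.6%, set WT replicate 3 apart from the other WT libraries. The WT larvae were w1118 and the Nxt1 larvae yw, so strain differed with genotype in every comparison. Feature lengths in the deposited values were out of order between genes (see the account of processing), so levels of different genes are not comparable. A ratio of FPKM within a gene holds, but a fold on FPKM + 1 depends on the length where values are low. The pre-mRNA log2 fold of Jhbp16 was -5.72 as deposited and -1.94 with lengths put back in order. The mRNA log2 fold of Alp8 was 4.54 by limma and 7.89 by edgeR on recovered reads, which no length enters. Sizes and ranks of the largest folds below are those under the deposited lengths.

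The targeted gene came first. Nxt1 mRNA (FBgn0028411) was 9.64 ± 1.22 FPKM in WT and 6.10 ± 0.429 FPKM in Nxt1 (SD, n = 3 each), or 63.3% of the WT level. Every Nxt1 library was below every WT library, with 346, 262 and 303 reads in WT and 93, 165 and 147 in Nxt1. The log2 fold was -0.58 (SE 0.106, limma adjusted p = 0.0164), and the 2-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The limma call was lost without WT replicate 1 (log2 fold -0.51, adjusted p = 0.0579), without Nxt1 replicate 1 (-0.57, 0.0576) and without Nxt1 replicate 3 (-0.54, 0.0645). Pre-mRNA of Nxt1 was listed at 0 in all 6 libraries. Of the pigmentation genes that mark the strains, white (w) had 0 reads in each WT library and 59, 114 and 101 reads in the Nxt1 libraries, and yellow (y) had between 1 and 5 reads in every library.

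To ask what the genotype did to mRNA levels, 8923 genes with a mean of at least 1 FPKM were tested with limma. Between the genotypes 1929 genes changed, 1117 higher and 812 lower in Nxt1, 501 of them by at least 2-fold. The largest rise was that of CG17105 (FBgn0032280), from 4.91 ± 4.91 to 1018 ± 176 FPKM (SD, n = 3 each), a fold of 215 on FPKM + 1 (limma adjusted p = 0.00151). The hexamerin storage protein gene Lsp1alpha (FBgn0002562) rose from 76.9 ± 69.2 to 1506 ± 416 FPKM (24.3-fold, limma adjusted p = 0.00680). The lysozyme gene LysD rose 57.8-fold, from 1.13 ± 0.347 to 209 ± 235 FPKM (SD, n = 3 each). Its rise was uneven, with 39, 1004 and 262 reads in Nxt1 replicates 1, 2 and 3. Other large rises were those of the noncoding lncRNA:CR40469 (34.0-fold), the synaptotagmin gene Sytalpha (23.6-fold), the alkaline phosphatase gene Alp8 (23.3-fold), CG11300 (22.3-fold) and the cuticle protein gene Cpr65Av (19.1-fold). Listericin (FBgn0033593), an antibacterial peptide gene, fell from 146 ± 32.1 to 8.40 ± 2.45 FPKM (0.0633-fold, limma adjusted p = 0.000899), and the odorant-binding protein gene Obp28a (FBgn0011283) fell from 615 ± 147 to 92.9 ± 35.9 FPKM (0.148-fold, limma adjusted p = 0.00491). The cytochrome P450 gene Cyp6a17 (0.0838-fold), the lysozyme gene LysP (0.109-fold), CG31262 (0.134-fold), CG8534 (0.135-fold), CG7888 (0.140-fold) and the cuticle protein gene Cpr47Eb (0.151-fold) fell as well.

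Of these 16 genes 15 kept their calls without any 1 library, and CG8534 lost its call without WT replicate 1 or Nxt1 replicate 1. The number of genes called was 772, 1557 and 2696 without WT replicates 1, 2 and 3, and 912, 767 and 774 without Nxt1 replicates 1, 2 and 3, against 1929 with all libraries. Scaling to equal totals of reads moved the median log2 fold of all genes to -0.32, from 0.01 with the deposited scaling, and then 528 genes rose and 4369 fell. Directions of gene groups below are those under the deposited scaling. Equal totals move all genes down alike, so the signs of list medians near 0 turn there with no change against other genes: 11 of the 29 medians went from above to below 0. Relative to the median of all genes, muscle attachment was at 0.29 with either scaling, autophagy at 0.11 and 0.10 with equal totals, hemocyte markers at 0.18 and 0.16, and ribosomal proteins at 0.02 and -0.01.

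Many genes of energy metabolism were higher in Nxt1, by a camera call that an estimated correlation between genes does not keep. Of 70 tested genes of oxidative phosphorylation, the mitochondrial ATP-producing chain, 47 rose and 0 fell (61 and 0 adjusted over the list alone), with a median log2 fold of 0.73 (camera adjusted p = 3.55e-16, and adjusted p = 0.55 with an estimated correlation). Among them COX6B rose from 227 ± 61.7 to 552 ± 32.8 FPKM (SD, n = 3 each), 2.49-fold, ATPsyndelta 2.33-fold, ATPsynD 2.28-fold and COX5A 2.24-fold. Of 13 glycolytic genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.72 (camera adjusted p = 5.11e-06, and adjusted p = 0.55 with an estimated correlation). Lactate dehydrogenase mRNA (Ldh) rose from 285 ± 115 to 1477 ± 204 FPKM (SD, n = 3 each), 5.45-fold, and Eno 4.81-fold, Pglym78 4.03-fold and Gapdh1 3.998-fold. With equal totals 22 genes of oxidative phosphorylation and 11 of glycolysis rose and 0 and 1 (Hex-A, named after its value was seen) fell, and the medians lay 0.71 and 1.67 above that of all genes.

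Muscle genes moved unevenly. Of 31 genes of the sarcomere and muscle structure 13 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 fold of 0.72 (camera adjusted p = 9.04e-05, and adjusted p = 0.55 with an estimated correlation). Under equal totals 6 rose and 4 fell (tn, tmod, TpnC41C and Strn-Mlck, named after their values were seen), with a median of 0.35 (0.67 above that of all genes, against 0.72 with the deposited scaling), and under quantile normalization 6 and 2, with a median of 0.51. The LIM protein genes Mlp60A and Mlp84B rose 4.12-fold and 2.48-fold, troponin C (TpnC47D) 3.61-fold and paramyosin (Prm), from 612 ± 156 to 1555 ± 65.1 FPKM (SD, n = 3 each), 2.59-fold. The muscle TRIM gene tn (FBgn0265356) was at 648 ± 48.3 FPKM in WT and 497 ± 87.2 FPKM in Nxt1 (SD, n = 3 each), 76.7% of WT, which missed the threshold (log2 fold -0.39, limma adjusted p = 0.110). Of 19 genes of muscle attachment and basement membrane 7 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00699, and adjusted p = 0.55 with an estimated correlation). Pax rose 2.05-fold, Tig 1.65-fold, Vinc 1.62-fold and the integrin gene if 1.603-fold. In the list of muscle calcium handling and excitation 4 of 18 genes rose and 3 fell (4 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.884). Its calcium pump gene SERCA rose 2.70-fold, its glutamate receptor genes GluRIIC and GluRIIE 1.74-fold and 1.72-fold, and its calcium channel gene Ca-alpha1T fell to 0.426 of WT. Under equal totals 1 gene of this list rose and 7 fell, and the calls of GluRIIC and GluRIIE were lost. Its median there lay 0.07 above that of all genes, against 0.10 with the deposited scaling.

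**Figure D1:**
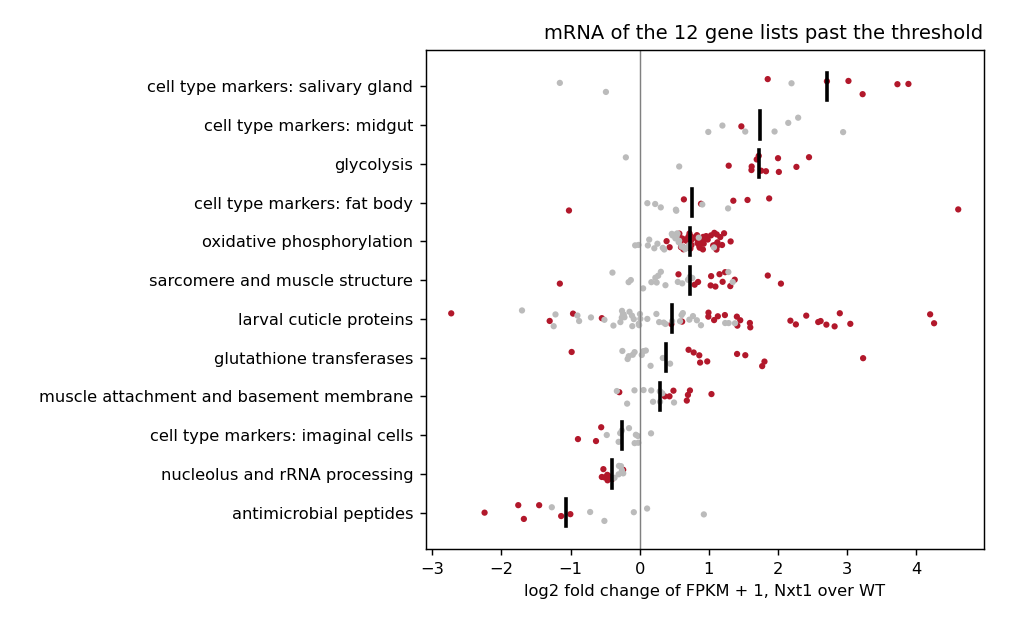
Log2 fold change of mRNA (FPKM + 1, Nxt1 over WT, 3 libraries each) for the tested members of the 12 gene lists past the camera threshold under the deposited scaling. Each point is a gene, red where its limma adjusted p is under 0.05, points are spread vertically for legibility only, and each black bar is the median of the list, from -1.07 for antimicrobial peptides to 2.71 for salivary gland markers; with equal totals the median of muscle attachment becomes -0.04, while that of all genes becomes -0.32.

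Markers of tissues other than muscle also differed between the genotypes, beside the groups above. Of 14 fat body markers 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 fold of 0.76 (camera adjusted p = 0.00169, and adjusted p = 0.55 with an estimated correlation). They included Lsp1alpha, Lsp1beta (3.66-fold), Fbp2 (2.94-fold) and the apolipophorin gene apolpp (2.56-fold). Of 9 salivary gland markers 6 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 2.71 (camera adjusted p = 0.0150, and adjusted p = 0.55 with an estimated correlation). The glue protein gene Sgs3 rose from 1.01 ± 0.691 to 19.1 ± 9.64 FPKM (SD, n = 3 each), 9.33-fold, and Sgs8 14.8-fold, Sgs7 13.2-fold and Sgs5 8.10-fold. With lengths put back in order 6 of 9 salivary gland markers rose, with a median of 3.04, and the adjusted p of the list was 0.0515. With edgeR on recovered reads 3 of these markers rose and 0 fell. Sgs7 and Sgs5 lost their calls there, and each also without 5 of the 6 libraries in turn. Of 8 midgut markers 1 rose, the maltase gene Mal-A6 (2.77-fold), and 0 fell (1 and 0 adjusted over the list alone), with a median of 1.74 (camera adjusted p = 0.0342, and adjusted p = 0.55 with an estimated correlation). The midgut call was lost under 9 of 19 alternatives, among them leaving out WT replicate 1 (median 1.48), WT replicate 3 (1.56), Nxt1 replicate 2 (1.4) or Nxt1 replicate 3 (1.52), and no filter (0.13). Alternatives without trend and with array weights leave camera unchanged, so under them no list call could be lost. Of 13 markers of imaginal cells, the precursors of adult tissues, 0 rose and 3 fell (0 and 5 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.0167, and adjusted p = 0.55 with an estimated correlation). Those were the homeobox genes Scr (0.539-fold), Antp (0.645-fold) and ap (0.680-fold), and the call was lost with equal totals (median -0.51, or -0.19 relative to all genes against -0.27 with the deposited scaling) and without WT replicate 1 (-0.11).

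Among 65 larval cuticle protein genes 23 rose and 4 fell (25 and 4 adjusted over the list alone), with a median log2 fold of 0.47 (camera adjusted p = 0.00198, and adjusted p = 0.55 with an estimated correlation). Cpr65Av, Cpr67Fa1 (18.4-fold), Cpr49Ah (8.25-fold) and Lcp2 (7.42-fold) rose most. In the glutathione transferase family, enzymes of detoxification, 10 of 22 genes rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00254, and adjusted p = 0.55 with an estimated correlation). Under equal totals 8 rose and 5 fell (GstE12, GstS1, GstT2, GstT4 and GstZ1, named after their values were seen), with a median of 0.09, or 0.42 above that of all genes against 0.38 with the deposited scaling. GstO3 rose from 37.0 ± 18.6 to 329 ± 12.2 FPKM (SD, n = 3 each), 9.38-fold, GstE6 3.49-fold, GstE3 3.41-fold and GstD1 2.88-fold. For antimicrobial peptides and their regulators 0 of 12 genes rose and 6 fell (0 and 6 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.00699, and adjusted p = 0.55 with an estimated correlation). Drs (0.211-fold), AttA (0.296-fold), Def (0.313-fold) and PGRP-SB1 (0.365-fold) fell. With equal totals 7 fell, with a median of -1.28 (-0.96 relative to all genes, against -1.08 with the deposited scaling), and the adjusted p of the list was 0.351. Genes of the nucleolus and of rRNA processing fell by less but together: 0 of 15 rose and 9 fell (0 and 12 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 5.11e-06, and adjusted p = 0.55 with an estimated correlation). Nopp140 (0.684-fold), Nop56 (0.695-fold), Nop60B (0.703-fold) and l(2)k09022 (0.722-fold) were lowest.

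The remaining lists did not pass the camera threshold. Within the mRNA export machinery sbr, which encodes the partner of Nxt1, rose from 98.3 ± 3.76 to 199 ± 8.99 FPKM (SD, n = 3 each), 2.02-fold (limma adjusted p = 0.00143), while nxf2 fell to 0.627 of WT and Nxt1 itself fell, so that 1 of 21 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.808). For the exon junction complex 0 of 11 changed (0 and 0 adjusted over the list alone, camera adjusted p = 0.808), with folds of 0.871 for Pnn and 0.871 for RnpS1 that did not pass. The circRNA biogenesis factor muscleblind (mbl) fell from 263 ± 21.4 to 174 ± 7.51 FPKM (SD, n = 3 each), 0.663-fold (limma adjusted p = 0.00881), and was the 1 gene of 13 in its list to change (0 and 1 adjusted over the list alone, camera adjusted p = 0.584). Among 20 genes of m6A and core splicing Ythdc1 rose 1.23-fold, with a log2 fold of -0.07 under equal totals, and x16 fell to 0.759 of WT (1 and 1 adjusted over the list alone, camera adjusted p = 0.884). In the RNA exosome and nuclear decay list Mtr4 was the 1 of 12 genes that fell, to 0.795 of WT (0 and 0 adjusted over the list alone, camera adjusted p = 0.178), and it lost its call without any of the 6 libraries in turn.

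Stress and turnover genes were mixed. Hsp68 rose 4.12-fold and the small heat shock gene l(2)efl 3.74-fold, while Hsp83 fell to 0.696 and Hsc70-4 to 0.776 of WT, so that of 17 chaperone genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.888, with a median of 0.02 and a test directed down). Of 20 autophagy genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.146), Atg8a by 1.63-fold, Atg18b by 1.48-fold, Atg9 by 1.48-fold and Atg3 by 1.40-fold. Under equal totals, which move all genes down, 0 autophagy genes rose and 6 fell, and the calls of these 4 were lost there and with the replicate block. Of 10 apoptosis genes Diap1 (0.706-fold), hid (0.757-fold) and egr (0.793-fold) fell and 0 rose (0 and 3 adjusted over the list alone, camera adjusted p = 0.0670). Among 34 proteasome genes Rpt6R alone passed, at 4.25-fold (1 and 0 adjusted over the list alone, camera adjusted p = 0.884). Of 81 cytosolic ribosomal protein genes RpL8 alone passed, at 1.23-fold, with a log2 fold of -0.07 under equal totals (0 and 0 adjusted over the list alone, camera adjusted p = 0.994). Under quantile normalization the list passed as a fall, with a median of -0.15 (-0.12 relative to all genes). It passed as a fall under equal totals as well, where 66 of 81 genes fell. Its median of -0.34 there lay close to that of all genes (-0.01 relative to it). In the ecdysone response MsrA (3.87-fold) and ImpE3 (1.65-fold) rose and the ecdysone-inactivating Cyp18a1 fell to 0.454 of WT, among 20 genes (2 and 1 adjusted over the list alone, camera adjusted p = 0.612).

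Other cell type markers gave no call as lists. Among 14 hemocyte markers 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.564): the prophenoloxidase genes PPO1 and PPO2 of crystal cells rose 4.67-fold and 4.42-fold, PPO3 of lamellocytes fell to 0.424 and the plasmatocyte receptor gene NimC1 to 0.472 of WT. Of 15 epidermal and tracheal markers mwh (3.68-fold), obst-E (2.54-fold) and dpy (1.88-fold) rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.152). Of 13 neuronal markers Syx1A rose 1.54-fold and nSyb fell to 0.754 of WT (1 and 1 adjusted over the list alone, camera adjusted p = 0.132). Of 6 oenocyte markers svp fell to 0.761 of WT (0 and 2 adjusted over the list alone, camera adjusted p = 0.216). Of 6 sex markers 0 changed (0 and 0 adjusted over the list alone, camera adjusted p = 0.966), with folds of 0.718 for fru and 1.32 for msl-2. Too few testis markers were measured for a list test, and CycB3 of that list fell to 0.689 of WT. Of 79 list members past the threshold and named here or above, 40 lost their calls without some 1 library.

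Pre-mRNA was compared next, since the study asks how precursor and mature RNA relate. Of 3576 genes with a mean of at least 1 FPKM, 30 rose and 23 fell in Nxt1 by limma, and 602 had an unadjusted p under 0.05. With edgeR on the recovered reads 208 genes passed. Several rises rested on many reads. The transporter gene NaPi-III had 32, 25 and 31 reads in WT and 128, 628 and 172 in Nxt1 (11.7-fold on FPKM + 1, limma adjusted p = 0.0336), and Ace, for acetylcholinesterase, had 31, 37 and 23 in WT and 68, 119 and 183 in Nxt1 (5.06-fold, limma adjusted p = 0.0160). CG13579 rose 7.05-fold, from 8, 15 and 9 reads to 34, 64 and 59. For GlyT, a glycine transporter gene, WT had few reads, 2, 2 and 3 against 17, 36 and 28 (12.6-fold). The histone pseudogene His-Psi:CR33867, a member of a multicopy cluster, fell from 136, 104 and 126 reads to 1, 4 and 2 (0.0257-fold).

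The other pre-mRNA genes named by the rule were near the floor in at least 1 genotype. Sytalpha, which also rose in mRNA, had 1, 1 and 0 reads in WT and 17, 52 and 32 in Nxt1. Its log2 fold hung on the pseudocount, 5.16 with 1 and 6.72 and 7.88 with 0.1 and 0.01, where the call was lost, and was 1.81 with lengths put back in order, where it was lost too. With edgeR on recovered reads, which no length enters, it was 5.805 and passed (edgeR adjusted p = 0.000626). Jhbp16, CG31102, Cpr67Fa1, CG5768, FucTA, Lgr3 and mei-218 had between 1 and 18 reads in each WT library and were listed at 0 in Nxt1, and yellow-f, alpha-Man-IIa and Spf30 were listed at 0 in WT with 1 to 3 reads in each Nxt1 library. Of the 16 genes 3 (CG31102, His-Psi:CR33867 and Lgr3) kept their calls without any 1 library. The number called was 19, 22 and 128 without WT replicates 1, 2 and 3, and 27, 6 and 15 without Nxt1 replicates 1, 2 and 3, against 53 with all. For tn pre-mRNA the values were 6956 ± 825 in WT and 7036 ± 1383 FPKM in Nxt1 (SD, n = 3 each, log2 fold 0.00360, limma adjusted p = 0.996), with a sign that turned under several alternatives. In pre-mRNA y was listed at 0 in WT and had 4, 2 and 1 reads in Nxt1, which did not pass.

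Of 23 lists tested on pre-mRNA 4 passed. The sarcomere list was higher in Nxt1, with a median log2 fold of 0.67 over 16 genes (1 rose and 0 fell, 6 and 0 adjusted over the list alone, camera adjusted p = 8.24e-05, and adjusted p = 0.548 with an estimated correlation), and Mlp84B in it rose 2.91-fold (limma adjusted p = 0.0370). The call of Mlp84B was lost without WT replicate 1 or 2 or any Nxt1 replicate. Ribosomal protein genes were lower, with a median of -0.36 over 40 genes (0 rose and 1 fell, 0 and 1 adjusted over the list alone, camera adjusted p = 0.00178, and adjusted p = 0.548 with an estimated correlation). The gene that fell, RpS19a, had 1 read in each WT library and was listed at 0 in Nxt1, and the list's call was lost without WT replicate 3 (median -0.23). Glycolysis was higher, with a median of 0.67 over 8 genes (0 rose and 0 fell, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0319, and adjusted p = 0.682 with an estimated correlation). Its call was lost without WT replicate 2 (median 0.48), Nxt1 replicate 1 (0.66) or Nxt1 replicate 2 (0.67). The ecdysone response was higher, with a median of 0.36 over 8 genes (1 rose and 0 fell, 3 and 0 adjusted over the list alone, camera adjusted p = 0.0319, and adjusted p = 0.548 with an estimated correlation), MsrA by 4.85-fold. The list's call was lost without WT replicate 3 (median 0.14) or without Nxt1 replicate 1, 2 or 3 (0.39, 0.37 and 0.32), and with quantile normalization (0.25). MsrA lost its own call without WT replicate 1 or 2 or any Nxt1 replicate.

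The ratio of mRNA to pre-mRNA within each library was tested in 3103 genes that passed both filters. By limma 6 ratios rose and 3 fell, 516 had an unadjusted p under 0.05, and edgeR on recovered reads called 217, of which 2 were among the 9. The balance of rises and falls depended on the scaling: 5 and 10 with quantile normalization, 7 and 10 with median-ratio rescaling, 19 and 86 with equal totals, and 91 and 126 with edgeR. Those 2, ATPsynC and CARPB, both had many intronic reads. ATPsynC, which encodes subunit c of the mitochondrial ATP synthase, gained 4.12-fold in ratio (limma adjusted p = 0.0261, edgeR adjusted p = 0.000129), and CARPB, a carbonic anhydrase-related gene, fell to 0.209 of the WT ratio (limma adjusted p = 0.000749, edgeR adjusted p = 2.72e-06). GILT3 fell to 0.342 with 3 to 11 intronic reads per library. The rises of Cpr67Fa1, mei-218, Lgr3, Vps35 and RpS19a and the fall of alpha-Man-IIa came from genes whose pre-mRNA was listed at 0 in all libraries of 1 genotype. Of the 9 ratios, those of Lgr3 and CARPB kept their calls without any 1 library, and that of ATPsynC was lost without WT replicate 1 or 2 or Nxt1 replicate 1 or 2. The number called was 3, 4 and 24 without WT replicates 1, 2 and 3, and 7, 5 and 10 without Nxt1 replicates 1, 2 and 3. The tn ratio had a log2 fold of -0.40 (limma adjusted p = 0.125).

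As lists, 3 of 23 passed in the ratio, all higher in Nxt1. Oxidative phosphorylation had a median log2 fold of 0.88 over 20 genes (1 rose and 0 fell, 6 and 0 adjusted over the list alone, camera adjusted p = 1.98e-06, and adjusted p = 0.133 with an estimated correlation). For glycolysis the median was 0.94 over 8 genes (0 rose and 0 fell, 6 and 0 adjusted over the list alone, camera adjusted p = 0.000147, and adjusted p = 0.218 with an estimated correlation). For cytosolic ribosomal proteins it was 0.34 over 40 genes (1 rose and 0 fell, 1 and 0 adjusted over the list alone, camera adjusted p = 0.000878, and adjusted p = 0.157 with an estimated correlation), and 0.09 with adjusted p = 0.135 under quantile normalization, where the call was lost. The remaining 20 lists did not pass.

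The change in ratio was lower in genes with long introns than in genes with short introns. The median log2 fold of the ratio went from 0.19 in the quintile with the shortest total intron length (up to 799 bases) to 0.11, 0.07, -0.00445 and -0.08 in the quintile with the longest (13229 bases and more), and Spearman's rho over 2722 genes was -0.202 (permutation p = 1e-05, the smallest that the permutations allow, Benjamini-Hochberg p = 1.5e-05 over 3 relations). Without any 1 library rho lay between -0.204 and -0.156. Within single libraries, rho of the ratio and intron length after centring each gene was 0.134, 0.0912 and 0.15 in WT and -0.174, -0.104 and -0.0269 in Nxt1 (exact permutation p = 0.1, the smallest possible for 3 against 3). For pre-mRNA rho was 0.0871 over 3120 genes (permutation p = 1e-05, Benjamini-Hochberg p = 1.5e-05), and 0.0273 (permutation p = 0.197) with edgeR on recovered reads. For mRNA it was -0.0433 over 7004 genes (permutation p = 0.00031, Benjamini-Hochberg p = 0.00031), but -0.007 without WT replicate 1 (p = 0.56) and 0.0026 without WT replicate 2 (p = 0.828). These relations are across genes, and genes are not independent replicates.

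**Figure D2:**
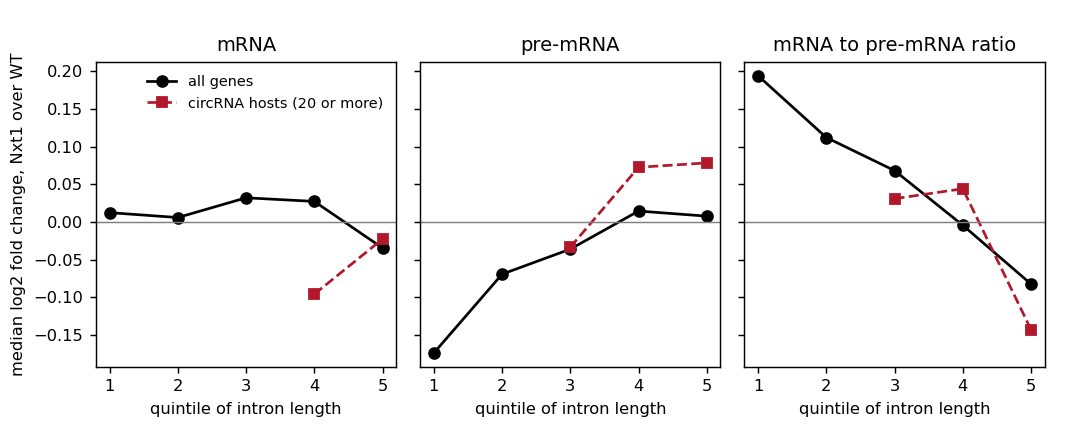
Median log2 fold change (Nxt1 over WT, 3 libraries each) of mRNA, pre-mRNA and their ratio by quintile of total intron length, from shortest (1) to longest (5). Black circles are all tested genes and red squares the genes that host a circRNA in WT, drawn where a quintile holds at least 20 hosts; the ratio of all genes goes from 0.19 in the shortest quintile to -0.08 in the longest.

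Host genes of circRNAs, the 445 genes named in the WT circRNA table, were compared with all other genes in their change of mRNA and pre-mRNA. Their mRNA did not differ by the test, with a median log2 fold of -0.04 in 436 hosts and 0.01 in other genes (limma camera p = 0.202, exact permutation p = 0.3 for the per-library difference below). The difference of -0.05 became -0.11 under quantile normalization, -0.09 against expression-matched genes and -0.09 without WT replicate 3, each past the threshold by limma camera, with the exact permutation test not repeated there. In pre-mRNA the hosts' median was 0.07 in 305 genes against -0.04 (camera p = 0.115, and p = 0.0375 with an estimated correlation). The change in the ratio of mRNA to pre-mRNA was lower in hosts, with a median log2 fold of -0.08 in 299 genes against 0.04 (camera p = 7.58e-05, and p = 0.0622 with an estimated correlation), although 0 single hosts passed by limma. Per library, after centring each gene, hosts minus other genes was 0.0748 ± 0.0312 in WT and -0.0590 ± 0.0299 in Nxt1 for the ratio (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). It was -0.0400 ± 0.0264 and 0.0333 ± 0.00721 for pre-mRNA (exact permutation p = 0.1) and 0.0345 ± 0.0619 and -0.0176 ± 0.0251 for mRNA (exact permutation p = 0.3). Centred values show the change between genotypes, not whether hosts lie above or below other genes within a genotype. Under quantile normalization the median log2 folds of hosts and other genes lay closer, with differences of 0.0177 in pre-mRNA and -0.0503 in the ratio. With the deposited scaling these differences were 0.113 and -0.127. By camera the ratio difference still passed the threshold under quantile normalization, and the pre-mRNA difference did not. Exonic reads of circles can count in the mRNA values of hosts, since the M libraries, read as mock-treated, keep circles. Such reads were not separated here from those of linear mRNA.

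Since 164 of the hosts with an intron length lay in the quintile with the longest introns for the ratio, the medians were also set against random lists. Among 10000 lists matched on expression, the hosts' change in ratio lay at percentile 0, and among lists matched on intron length at percentile 0.05. The difference from other genes was not uniform: within quintiles of intron length it was -0.04 in the third (24 hosts), 0.06 in the fourth (62 hosts) and -0.10 in the fifth (164 hosts), which was not tested. Their pre-mRNA lay at percentiles 99.9 and 99.3, and their mRNA at 0 and 17.7. The matched sets held 87.4% of hosts for mRNA, 86.9% for pre-mRNA and 87.0% for the ratio. These percentiles measure the spread of drawing genes, taken as independent, and not the spread between libraries.

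CircRNAs were read in the R libraries. The WT table listed 597 circRNAs from 445 genes, and that of Nxt1 listed 467 from 366 genes. Each circRNA came with the reads of 2 of the 3 libraries of its genotype, and how these were picked is not given. Both tables listed 335 circRNAs, 56.1% of those in WT and 71.7% of those in Nxt1, and 302 host genes. The most abundant circle of both genotypes came from exon 2 of the laccase gene stw, at 80540 back-splice reads per 1e+09 library reads (below, scaled reads) in WT and 71500 in Nxt1. Next were exons 2 to 4 of the glycogenin gene Gyg, at 46670 and 40670, and exon 7 of tn, at 28200 and 16840 scaled reads (1879 and 2270 reads in WT, 780 and 1248 in Nxt1). Circles of larp, tai, Pka-C3, IRSp53 and Pde8 followed in WT, between 15540 and 5791 scaled reads. Exons 6 to 9 of mbl gave 4 and 22 reads in WT and 25 and 6 in Nxt1, and the circle of mbl exons 5 and 6 was listed in WT alone, with 27 and 15 reads. Other circles of tn were each listed in 1 genotype alone with 22 reads or fewer per library. Absence from a table is not a count of 0, since the rule for listing is not given. A circle named by another transcript would also count as absent.

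Among the 335 circRNAs of both tables edgeR called 9 higher and 12 lower in Nxt1. The largest rise was that of exon 9 of Sarm, an NADase gene of axon degeneration, with 18 and 5 reads in WT and 322 and 447 in Nxt1, a ratio of 43.2 in scaled reads (edgeR adjusted p = 1.28e-06). Its host mRNA had a fold of 1.01 (limma adjusted p = 0.961). Exons 3 to 5 of Lmpt rose 10.7-fold, from 21 and 28 reads to 165 and 219 (edgeR adjusted p = 8.09e-05), with a host mRNA fold of 1.32 that missed the threshold (limma adjusted p = 0.0568). Circles of mol (exons 2 to 4, 6.07-fold), grh (exon 2, 6.03-fold) and Rgk3 (exons 3 to 6, 5.92-fold) rose too. The circle of magu exons 6 to 8 fell from 66 and 58 reads to 3 and 2 (0.0396 of WT, edgeR adjusted p = 0.00569), with a host mRNA fold of 1.40 (limma adjusted p = 0.0625). Circles of Hs6st (exons 3 to 5, 0.111 of WT), seq (exon 3, 0.1202), CG43759 (exons 5 and 6, 0.121) and the kinase gene Src42A (exon 2, 0.123) fell as well, and of these hosts Src42A also fell in mRNA, to 0.699 of WT (limma adjusted p = 0.0172). Of the 9 circles that rose 1 had a host mRNA that rose, and of the 12 that fell 3 had a host that fell and 2 a host that rose.

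Of these 10 named circles, those of Sarm and Lmpt kept their calls whichever 1 of the reads columns was left out. Leaving out the first or second column of WT gave 8 and 19 calls, and the first or second of Nxt1 12 and 7, against 21 with all. Scaling by the circRNA reads themselves gave 43 (27 higher and 16 lower with TMM factors), with a median log2 fold of 0.03 against -0.26 under library totals. The library effects on shared circRNAs were 0.115 ± 0.176 in WT and -0.115 ± 0.36 in Nxt1 on the log2 scale (SD, n = 3 each, exact permutation p = 0.4, with 0.1 the smallest possible). A difference in the level of shared circRNAs was thus within the spread of the libraries. CircRNAs listed in 1 genotype alone do not enter these effects, so a general difference in circRNA level was not tested.

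**Figure D3:**
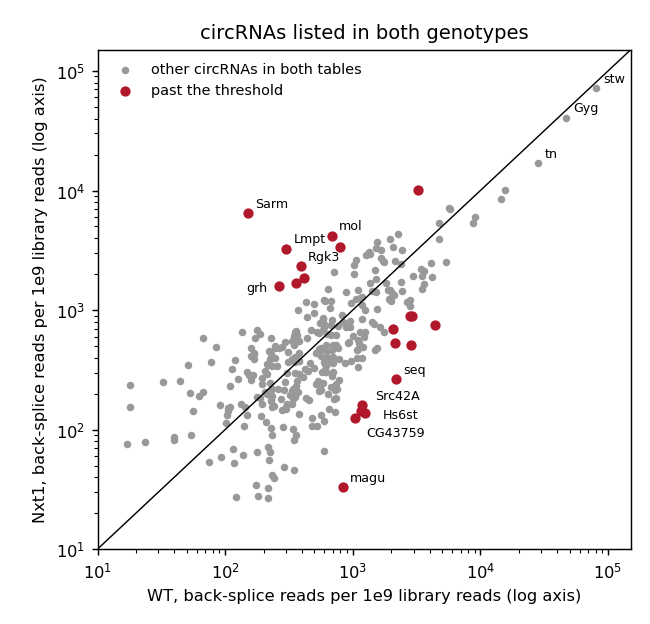
Level of each of the 335 circRNAs listed in both genotypes, in back-splice reads per 1e+09 library reads (mean of 2 libraries, by the authors), WT on the horizontal and Nxt1 on the vertical log axis. Red points passed edgeR's adjusted p of 0.05 (9 higher and 12 lower in Nxt1 with library totals), the line marks equal levels, and the named points include Sarm at 150 and 6475 and magu at 835 and 33.0.

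CircRNAs of 1 exon were 194 of 597 in WT (32.5%, 95% Clopper-Pearson interval 28.7% to 36.4%) and 138 of 467 in Nxt1 (29.6%, 25.4% to 33.9%), with Fisher's exact p = 0.318. For the classes of 1, 2 and 3 or more exons Fisher's exact p was 0.588, and 45.9% of WT and 45.8% of Nxt1 circRNAs started at exon 2 (Fisher's exact p = 1). The tables share 335 circRNAs, which the test takes as separate, so these p values do not show that the structures are alike. The intervals cover counting error only. Among shared circRNAs the median log2 ratio was -0.54 for 105 of 1 exon, -0.24 for 134 of 2 exons and -0.16 for 96 of 3 or more, a difference not tested.

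CircRNA change was weakly related to the change of the host's mRNA across 274 genes. Pearson's r was 0.127 (permutation p = 0.0354, Benjamini-Hochberg p = 0.106 over 3 relations) and Spearman's rho 0.153 (permutation p = 0.0113, Benjamini-Hochberg p = 0.0339), and without Nxt1 replicate 2 of the M libraries rho was 0.133 with a Benjamini-Hochberg p of 0.0858. Against host pre-mRNA in 196 genes rho was 0.127 (permutation p = 0.0767, Benjamini-Hochberg p = 0.115), and 0.156 with a Benjamini-Hochberg p of 0.0444 without WT replicate 3. For the ratio of mRNA to pre-mRNA in 195 genes rho was -0.0228 (permutation p = 0.752, Benjamini-Hochberg p = 0.752). As exonic reads of circles can count in host mRNA, circRNA and host mRNA values are not fully separate measures.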

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

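Of the tests in this part, those of scaling for the glycolysis and sarcomere genes and for the lead of lists over all genes, of the muscle share, of the reordered lengths, of both circRNA explanations and of the splits of the libraries were chosen after the result was seen. In the pre-mRNA values 1757 genes were given as infinite in at least 1 library, that is, with reads over a length of 0 that belonged to another gene: a signal in values that no comparison here uses. Each library held between 1353 (Nxt1 replicate 1) and 1500 (WT replicate 2) of them, and their reads cannot be recovered.

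Genes of oxidative phosphorylation, glycolysis and the sarcomere were higher in Nxt1 by camera, although each of the 3 calls was lost with an estimated correlation (adjusted p = 0.55), and of 31 sarcomere genes 13 rose and 1 fell. A factor per library moves all genes alike, so their lead over all genes is no test of scaling by such factors. Quantile normalization is no such factor, and with it the medians lay 0.7 (oxidative phosphorylation, quartiles 0.59 and 0.86) and 0.542 (sarcomere, quartiles 0.13 and 0.85) above that of all genes. This argues against a difference between libraries shared by all genes of like deposited FPKM, which quantile normalization takes out, as the whole cause. It does not test other forms of scaling. All 11 glycolytic genes that had risen still rose with equal totals. How many single genes of the other lists rose stays open to scaling, since 22 of 47 of oxidative phosphorylation and 6 of 13 of the sarcomere still rose with equal totals, between the bounds set for the tests. The lists of muscle genes did not move alike, with a sarcomere median of 0.72 (quartiles 0.26 and 1.18) against 0.11 (-0.21 and 0.31) for calcium handling and excitation (1-sided permutation p = 0.00451). That does not decide on a larger share of muscle, since whether muscle alone expresses the second list was not known. The permutation also takes genes as independent, while the estimated correlations were 0.33 and 0.204. Larval timing or tissue left after dissection may contribute and cannot be told apart from genotype here (in 0 of the 3 lists was the WT library with the most salivary gland markers also the highest, but 1 library excludes nothing), and strain and the Nxt1 genotype itself stay open, untested.

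The change in the ratio of mRNA to pre-mRNA, Nxt1 over WT, was lower the longer the introns. Few intronic reads in genes with short introns are argued against as the cause, since rho was -0.208 in 1364 genes with a mean of at least 50 intronic reads per library. The lengths out of order are argued against by recovered reads, which no length enters (rho -0.217 in 2212 genes), and the genes of the fixed lists by rho without them (-0.179 in 2524 genes), each with a permutation p of 1e-05, the smallest the permutations can give. An effect of Nxt1 on the balance of precursor and mature RNA of genes with long introns is a candidate explanation, but strain, larval timing and tissue make-up were not separated from it.

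Fewer circRNAs were listed in Nxt1. Sequencing depth is argued against as the whole cause, provided that a circle carries the same name in both tables. Of 275 circRNAs with at least 50 reads in WT, 46 were missing from the Nxt1 table (42 also by gene and exon numbers). At least 35.6 reads were expected for each of these in the 2 smallest Nxt1 libraries. Of 186 circRNAs with at least 50 reads in Nxt1, 9 were missing from the WT table. A circle named by another transcript with other exon numbers would count as missing, which could not be checked without coordinates. Spread between libraries stays open, since the library effects on shared circRNAs overlapped, with a mean difference of -0.23 on the log2 scale (exact permutation p = 0.4). The rule for listing a circRNA is not given and may also differ between the tables.

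With 10 splits of the 6 M libraries into groups of 3, in each comparison 1 split, the real one, gave as many calls as it did, and the splits are too few for a share under 0.05. For mRNA the real value was 1929 calls and the highest other 0, for pre-mRNA 53 and 4, and for the ratio 9 and 6.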

How the results depend on the processing

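Alternatives with edgeR on recovered reads, equal totals, lengths put back in order, circRNA library effects taken out and matching by gene and exon numbers were chosen after seeing the data. So were most alternatives of the targeted gene, the libraries left out for the relations across genes, and for lists and hosts the pseudocount of 0.01, median-ratio rescaling, eBayes without trend and array weights. Of 259 results of comparisons under alternatives, 194 kept direction and side of the threshold (or a count within 1.5 times), 8 lost the threshold, 7 gained it, 49 counts moved and 1 reversed. Of 2355 results of named genes 1953 were the same, 382 lost the threshold, 12 gained it and 8 reversed; of 90 of named circRNAs 71 were the same and 19 lost it; of 676 of single lists 500 were the same, 47 lost it, 8 gained it, 119 counts moved and 2 reversed. For lists and hosts, eBayes without trend and array weights do not enter camera, so its result was the same by construction. Median-ratio rescaling nearly repeats the deposited scaling of mRNA. Results counted as the same under these alternatives are no sign of stability. The cause of a change was not tested unless given here.

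Replicate numbers did not pair the libraries: after removal of the genotype means, the same number in both genotypes correlated at -0.081, -0.12 and -0.29 in mRNA and 0.0068, 0.036 and 0.0038 in pre-mRNA. With the replicate block the targeted gene was at -0.578 (adjusted p = 0.0749), and 585 mRNA, 0 pre-mRNA and 1 ratio calls and 12, 2 and 3 lists were left; the block takes residual degrees of freedom. For the circRNA results no paired analysis was possible because their columns mix libraries without replicate numbers. Array weights gave 4229 mRNA, 131 pre-mRNA and 31 ratio calls. Equal totals gave 4897 mRNA and 105 ratio calls, with the median of all genes moved to -0.32. Lengths put back in order gave 27 pre-mRNA and 2 ratio calls, and edgeR 208 and 217. Ratio calls were 22 with either pseudocount (0.1 or 0.01), 30 with no filter, 2 with a mean of at least 5 FPKM, 15 with quantile normalization, 17 with median-ratio rescaling and 15 without trend.

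Lists passing fell to 0, 0 and 0 in mRNA, pre-mRNA and ratio with an estimated correlation, and were 0 in pre-mRNA and 6 in the ratio with fry. In mRNA, fry gave adjusted p = 0.0408 for oxidative phosphorylation, 0.0278 for glycolysis and 0.0432 for the sarcomere. Midgut markers lost their call with fry (adjusted p = 0.0979). As fry tests a list against no change, it does not show a lead over other genes. Ribosomal proteins, with a median of 0.0323 and no call, passed with a median of -0.154 under quantile normalization and -0.336 under equal totals, where that of all genes was -0.32. Hosts differed by -0.106 in mRNA under quantile normalization and -0.0881 against expression-matched genes, both past the threshold. Under quantile normalization their difference shrank in pre-mRNA from 0.113 to 0.0177, not past the threshold. In the ratio it shrank there from -0.127 to -0.0503, still past the threshold. With equal totals hosts differed by 0.105 in pre-mRNA, not past the threshold. In pre-mRNA they differed by 0.113 with an estimated correlation (p = 0.0375), and by 0.138 with hosts of either table (p = 0.0340), past it, and in the ratio by -0.127 with an estimated correlation (p = 0.0622), not past it. The test by fry, which allows for correlation between genes but sets hosts against no change and not against other genes, gave p = 0.0243 in pre-mRNA. CircRNA calls were 43 with TMM and 43 with DESeq2 factors, 38 with the DESeq2 Wald test and 44 with library effects taken out, and each of these held all 21; no filter removes none and moves nothing. Intron length and pre-mRNA gave 0.0273 with edgeR. Under equal totals RpL8 was at -0.0713 and Ythdc1 at -0.0688. The log2 fold of tn pre-mRNA was -0.143 with quantile normalization, -0.12 with equal totals, -0.0131 with edgeR, and from -0.12 to 0.168 without any 1 library, below 0 without WT replicate 3 or Nxt1 replicate 2 or 3.

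Without any 1 of the M libraries, the targeted gene lay between -0.671 and -0.507, mRNA calls between 767 and 2696, pre-mRNA calls between 6 and 128, ratio calls between 3 and 24, lists between 10 and 13, 2 and 4, and 3 and 4, host differences between -0.0867 and -0.026, 0.0696 and 0.11, and -0.151 and -0.0926, the relation of circRNAs (all reads columns kept) to host mRNA between 0.133 and 0.166, to host pre-mRNA between 0.108 and 0.156 and to the ratio between -0.0694 and -0.00195. Intron length gave -0.11 to 0.0026 for mRNA, 0.0432 to 0.11 for pre-mRNA and -0.204 to -0.156 for the ratio. No R library was left out, since each circRNA column mixes libraries. Leaving one out circRNA by circRNA, told by its library total, was not done. Without any 1 of the 4 reads columns, circRNA calls lay between 7 and 19. A lone circRNA column in a group is assumed to vary like the other group's. In simulated reads at these depths 59.2% of 2-fold changes were called in mRNA by limma, against 9.18% in pre-mRNA, 4.12% in the ratio and 3.45% in circRNAs by edgeR.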
